A study of Drosophila melanogaster with 4 samples.

How the data were processed

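Anti-GFP CUT&RUN, an assay in which an antibody-tethered nuclease releases DNA fragments at the sites an antibody marks, was run on wing imaginal discs of female Drosophila melanogaster larvae at the wandering stage. Osa is the subunit that defines one class of SWI/SNF (Brahma-associated) nucleosome remodeler. There were 2 libraries from larvae with GFP-tagged Osa (Osa-GFP) and 2 from yw larvae, which carry no GFP and give the background of the antibody and nuclease. Per the labels' protocols, animals grew at 25 °C, 20 to 22 discs were dissected per replicate, and libraries were made from the supernatant fraction. The labels do not say whether the dissections came from separate crosses, so the spread between replicates may be partly technical. The series record states that sample titles were corrected in an update; the corrected titles were used.

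Each library was represented by 1 deposited peak list in narrowPeak form on genome build dm6. Per the submitters' processing notes, the tools were Bowtie2 2.3.4.1, SAMtools 1.10, Picard 2.2.4, deepTools 2.4.1 and MACS2 2.1.2. The deposited peak names carry tags for trimming, a mapping quality filter, removal of duplicates and the use of all fragment lengths, and 1 name per library, so peaks were called per library and not on pooled replicates. The command line and the calling threshold are not given in the sources used here. The deposited fold of each peak is a ratio of fragments over background at the summit, computed by the authors' peak caller. The deposited p and q are given as −log10 values. The deposited integer score is 10 times the −log10 q, cut to a whole number, and was not used further. The last deposited column gives the summit's distance from the peak start, a position rather than a measurement. A peak's fold is the caller's own value and was used only to describe, rank or filter peaks within its list.

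The deposited files give no total read counts. Within each list the deposited folds were whole multiples of 1 step, as they are if fold equals summit fragments plus 1, divided by background plus 1. This gave whole summit fragment numbers for 100% of peaks at a tolerance of 0.01. A Poisson probability from those fragments and 1 background per library returned the deposited −log10 p to within 6.63e-06 for all peaks with a −log10 p under 100, so the deposited values need neither a control library nor a local background. The recovered background, the mean number of fragments over a position, was 0.472 and 0.460 in Osa-GFP replicates 1 and 2 and 0.120 and 0.481 in yw replicates 1 and 2. It is the measure of depth used here: yw replicate 1 was 4.00 times shallower than yw replicate 2.

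Peaks on the 6 arms 2L, 2R, 3L, 3R, 4 and X were merged across the 4 libraries wherever they overlapped by 1 bp or more. A region was called Osa-GFP-specific if it held a peak of both Osa-GFP libraries and of neither yw library. It was called shared if it held a peak of both Osa-GFP libraries and of at least 1 yw library, and yw-only if it held a yw peak and no Osa-GFP peak. Overlap between lists was set against 100 seeded shuffles of one list within its arms. Shares carry 95% Wilson intervals, which cover counting error only, since fragments after PCR and neighbouring peaks are not independent. With 2 libraries against 2 there are 6 assignments and the smallest two-sided exact p is 0.33, so a test across libraries cannot establish a difference. Such tests are given only for the share of peaks near gene ends, and no conclusion was drawn from them. Tests across regions or genes describe these lists; regions and genes are not replicates.

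Gene positions came from a RefSeq gene table of 17872 rows on the same assembly, which gives gene spans without strand. The design written before the data were examined used transcription start sites. Because strand was not given, either end of a gene's span was used in place of its start site: regions within 500 bp of a gene end were counted, and each region was assigned to the protein-coding gene with the nearest end. Distances run from the region's centre. Introns, exons and UTRs were not told apart. This rule is the closest to the written design, but it was settled with the list results under 4 assignment rules in view; all 4 are reported. No genome sequence was used, so the planned search for motifs under the summits was not run.

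For 20 gene lists fixed before the data were examined, the number of members with 1 or more regions was compared with all 13922 protein-coding genes on the 6 arms. The lists covered wing regional identity, vein and intervein fate, the Notch, Wg, Dpp, Hh and EGFR pathways, Hippo pathway and growth, ecdysone response, proneural and sensory organ genes, Hox genes and SWI/SNF subunits. They also covered cytosolic ribosomal proteins, chemoreceptors and markers of adult muscle precursors, trachea, hemocytes, neurons, germline and fat body. The test was an exact stratified hypergeometric test, two-sided by doubling, with 20 bins of territory size as strata. A gene's territory is the stretch of genome closer to its ends than to those of any other gene. Size was not corrected within a bin, and the bin of the largest territories has no upper limit, so the correction is coarse there. P values were adjusted over the 20 lists by Benjamini-Hochberg, with 0.05 as the threshold. Older symbols were matched to current ones (Dl to Delta, phl to Raf, h to hry, d to dachs, duf to kirre, nos to nanos); 1 name, taiman, had no match of its own and is the gene listed as tai. Tests of the difference between Osa-GFP-specific and yw regions in their share at each list were added after the list tests had been seen. They used 100000 random lists matched on territory bins and were run against all regions with a yw peak and against yw-only regions.

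The genes named follow a rule fixed before the data were examined. It takes the 10 Osa-GFP-specific regions, the 5 regions with peaks of all 4 libraries and the 5 yw-only regions of both yw libraries that come first by the worse of their within-list ranks. It also takes up to 4 members of each list with the most Osa-GFP-specific regions, and nub, br, Delta, vg, ct and osa whatever their values. A few other list members are named only to say which genes made up a count. Alternatives covered the peak threshold, the rule of overlap, the number of peaks per list, the use of the yw libraries, the window around gene ends, the gene assignment, the correction for territory size and leaving out each library.

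Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The code was tested on simulated data: 717 of 717 planted Osa-GFP-specific regions were recovered. The planted sites lay farther apart than their peaks were wide, and the peaks of a site shared the same centre. Full recovery thus checks the code and not regions that lie close together. With 13922 genes simulated, a list raised 2.5-fold, or as far as all members allow, was called in 99.5% of 200 simulations for wing regional identity (28 genes), in 42.5% for the Notch pathway (25 genes) and in 0.5% for the Hh pathway (11 genes). Any list that had not been raised was called in 1% to 3% of them. The simulated genes were drawn independently of each other. The real regions lay close together and some lists hold neighbouring genes, so these rates need not hold for the real lists.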

Results

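Genome-wide anti-GFP CUT&RUN peaks were compared between wing discs with GFP-tagged Osa and discs without GFP, with 2 libraries per genotype. The question was where in the wing disc genome the SWI/SNF subunit Osa sits above what the same antibody returns with no GFP present. On the 6 main arms the lists held 5820 and 4987 peaks in Osa-GFP replicates 1 and 2 and 774 and 4535 peaks in yw replicates 1 and 2. Depth, as the background recovered from the caller's folds, was 0.472, 0.460, 0.120 and 0.481 fragments per position in that order. yw replicate 1 was thus the shallow library and the other 3 had similar depth. Peaks with −log10 q of 10 or more numbered 2075, 1619, 76 and 776. Median peak width was 266 and 268 bp in the Osa-GFP lists and 194 and 209 bp in the yw lists.

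The strongest regions that both Osa-GFP libraries held and neither yw library held are given here in order of the worse of their within-list ranks. The first was inside schnurri (shn), a zinc finger protein of Dpp signalling, on 2R at 11180806 to 11182227, with caller's folds of 45.5 and 37.7 in Osa-GFP replicates 1 and 2. It was followed by a region in the teneurin gene Ten-a on X at 12225752 to 12227126 (42.8 and 38.3) and one in scribbler (sbb), a nuclear regulator of patterning, on 2R at 18304181 to 18305337 (42.8 and 32.2). The next were in CG10939, taranis (tara), CG42673, CG42238 and ko. The ninth region was centred 4535 bp outside wingless (wg), the Wnt ligand of the wing margin, on 2L at 7319686 to 7321914 (30.6 and 23.3). The tenth was in Prosap, a scaffold protein gene. These names go by gene span; by nearest gene end, the regions inside shn, Ten-a, sbb and ko belong to other genes.

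Merging the 4 lists gave 9599 regions, of which 3344 held peaks of both Osa-GFP libraries. Of these, 1765 were Osa-GFP-specific and 1579 were shared with at least 1 yw library, a share of 47.2% (95% interval 45.5% to 48.9%). Almost all shared regions held a peak of yw replicate 2; only 29 held a peak of yw replicate 1 alone. There were 1954 regions of Osa-GFP replicate 1 alone, 1182 of Osa-GFP replicate 2 alone and 2611 yw-only regions, of which 48 held peaks of both yw libraries. Median width was 402 bp for Osa-GFP-specific, 661 bp for shared and 171 bp for yw-only regions. The count of specific regions depends on the deeper control: without yw replicate 2 it was 3055, and with −log10 q of 10 or more in every library it was 1001. With 1 Osa-GFP library in place of both it was 3863 (replicate 1) or 3154 (replicate 2), since no second library then had to hold the peak.

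The strongest regions with peaks of all 4 libraries lay outside the spans of protein-coding genes. The first was on X at 22433011 to 22433197, centred 11123 bp from CG14621, with caller's folds of 158, 175, 137 and 198 in Osa-GFP replicates 1 and 2 and yw replicates 1 and 2. The second and the third were neighbours near CG40228 on 3L, at 27078119 to 27079563 and 27073997 to 27075345. The fourth was centred 83519 bp from the mitochondrial ribosomal protein gene mRpS5, and the fifth was 39084 bp from scarecrow (scro), a homeobox gene, both on 3L. In all, 267 regions held peaks of all 4 libraries. The strongest regions of both yw libraries and no Osa-GFP library were in CG3408, in the metal-responsive transcription factor gene MTF-1, in sano, in Su(var)2-10, a SUMO ligase gene, and beside tinc.

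Peaks of the Osa-GFP libraries met each other more often than they met yw peaks of a library of like depth. Of the Osa-GFP replicate 1 peaks, 60.3% (59.0% to 61.5%) overlapped a peak of Osa-GFP replicate 2 and 32.9% (31.7% to 34.1%) a peak of yw replicate 2. The Jaccard index in bases was 0.481 for the Osa-GFP pair, 0.194 and 0.205 for yw replicate 2 with Osa-GFP replicates 1 and 2, and 0.0694 for the yw pair. Shuffled lists reached at most 3.44% and 2.84% for the first pair of values. Of the peaks of the shallow yw replicate 1, 48.8% overlapped yw replicate 2, 43.9% Osa-GFP replicate 1 and 42.5% Osa-GFP replicate 2, and the 95% intervals of these 3 values met (45.3% to 52.4%, 40.5% to 47.4% and 39.1% to 46.0%). Only 3 groupings of 4 libraries into pairs exist, so no p under 0.33 can be had for this comparison.

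**Figure D1:**
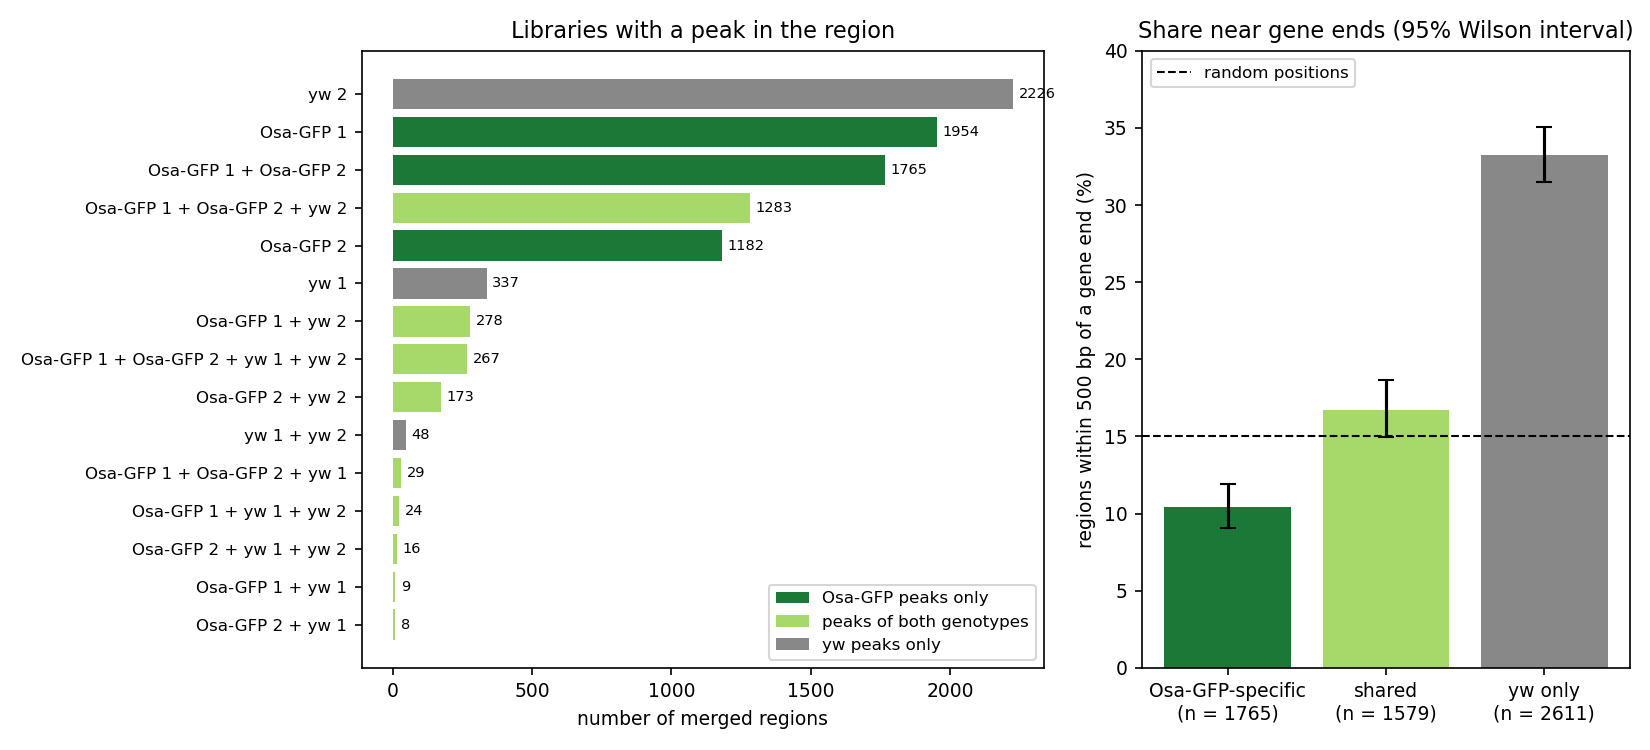
Left, number of merged regions (x axis) for each combination of libraries with a peak (y axis). Right, percentage of regions centred within 500 bp of either end of a protein-coding gene, with 95% Wilson intervals and the share of random positions as a dashed line; the 1765 Osa-GFP-specific regions lie at 10.4%, the shared regions at 16.7% and the yw-only regions at 33.2%.

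Osa-GFP-specific regions were centred near gene ends less often than shared or yw-only regions. Of them, 10.4% (9.08% to 11.9%) were centred within 500 bp of an end of a protein-coding gene, against 16.7% (15.0% to 18.6%) of shared and 33.2% (31.5% to 35.1%) of yw-only regions; random positions gave 15.0%. The difference of -6.29 percentage points between specific and shared regions had a two-sided Fisher's exact p of 1.11e-07. These 2 sets differ by definition in whether a yw peak was called, and yw peaks were frequent near gene ends. The test therefore cannot tell where Osa lies from where yw peaks were taken out. Specific and shared regions together gave 13.4% (12.3% to 14.6%). Per library, the share was 14.7% and 13.8% in the Osa-GFP lists and 22.0% and 27.7% in the yw lists. Examples far from gene ends were a region inside homothorax (hth), 39620 bp from its nearer end, and one inside frizzled 2 (fz2), 41110 bp from it; hth encodes a homeodomain protein of the wing hinge and fz2 a Wg receptor. The difference between specific and shared regions was smaller without yw replicate 2, at -2.17 points (Fisher's exact p = 0.28). At −log10 q of 10 or more in every library it was -1.20 points (exact p = 0.53).

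Genes that pattern the wing held Osa-GFP-specific regions more often than genes in the same territory bins. Of the 28 genes of wing regional identity, 20 were the nearest gene of at least 1 such region where 8.21 were expected (adjusted p = 5.6e-05, exact stratified hypergeometric test). hth had 16 regions, the selector tailup (tup) of the notum 6, caupolican (caup) of the Iroquois complex 5 and nubbin (nub), a POU factor of the wing pouch, 4. Of 20 vein and intervein genes, 16 had a region where 6.17 were expected (exact test, adjusted p = 5.6e-05). They included the T-box gene bi with 6 and, with 5 each, the Notch ligand gene Delta, the POU gene vvl and blistered (bs), which sets intervein fate. The strongest region assigned to bs was on 2R at 24338032 to 24339400, centred 4145 bp from the gene, with caller's folds of 16.3 and 10.3 in Osa-GFP replicates 1 and 2. At vestigial (vg), which selects wing identity, 2 specific regions were found, the stronger inside the gene on 2R at 12888555 to 12889802 (20.4 and 17.8).

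More genes of the Wg, EGFR and Notch pathways and of the ecdysone response had an Osa-GFP-specific region than expected from their territory bins. Of 22 Wg pathway genes, 12 had a specific region (4.85 expected, exact test, adjusted p = 0.0030), among them fz2 with 8, the feedback antagonist naked cuticle (nkd) with 5, and the glypican gene dlp and the receptor gene fz3 with 4 each. Of 16 EGFR pathway genes, 10 had one (3.79 expected, exact test, adjusted p = 0.0030): the kinase gene Raf had 6, the inhibitor gene kek1 and the repressor gene capicua (cic) 5 each, and sprouty (sty) 3. Of 25 Notch pathway genes, 9 had one (3.49 expected, exact test, adjusted p = 0.0071), with 4 each at the receptor gene N and the glycosyltransferase gene fringe (fng) and 3 at the protease gene kuz. Of 22 ecdysone response genes, 14 had one (5.18 expected, exact test, adjusted p = 0.00014), with 5 at chinmo and 3 each at Eip74EF, Eip75B and the coactivator gene tai. Lists shared members. The genes rho, vn, aos and pnt counted for veins and for EGFR, and Delta for veins and for Notch. In the same way br counted for wing identity and for ecdysone response, and ush for wing identity and for hemocytes.

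The other signalling lists did not pass the threshold. They were Dpp with 5 of 15 genes, Hh with 3 of 11 and Hippo pathway and growth with 6 of 16, each at an adjusted p of 0.109 in the exact test. Their side of the threshold was not firm: Dpp passed in 7 of the 10 alternatives, Hippo in 7 and Hh in 4. Their members with most regions were the protocadherin gene dachsous (ds) with 9, the ligand gene hh with 4, and dpp and its antagonist sog with 3 each. The proneural list had 2 of 15, the Hox list 4 of 8 and the SWI/SNF list 1 of 12, which was osa itself with 2 specific and 5 shared regions. Among lists of other tissues, trachea passed with 5 of 8 (1.56 expected, exact test, adjusted p = 0.027), led by the chitin deacetylase genes serp with 3 and verm with 2. Counts that did not pass were 3 of 10 for adult muscle precursors, 3 of 11 for hemocytes, 1 of 10 for germline, 0 of 12 for neurons and 0 of 10 for fat body. They were also 3 of 89 for cytosolic ribosomal proteins and 5 of 179 for chemoreceptors (11.3 expected, exact test, adjusted p = 0.0901), which passed with fewer genes than expected in 6 of the 10 alternatives.

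Of all 13922 genes, 954 had at least 1 specific region and 418 had 2 or more. Only overlapping peaks were merged, so the counts per gene include specific regions that lie close beside a shared one. At dlp on 3L, the strongest specific region ran from 14633982 to 14634418 and the strongest shared region from 14634558 to 14635629. How often this occurred was not counted. The wing identity call was lost at −log10 q of 10 or more and the trachea call under 6 of the 10 alternatives, and no list passed when only the 184 regions within 500 bp of a gene end were counted. There 6 of the 7 lists still lay above their expectation, on at most 3 genes each, such as vein fate at 3.72 times and wing identity at 2.65 times. Without yw replicate 2, 11 lists passed, 9 with more genes than expected and 2, chemoreceptors and neurons, with fewer. By gene body with 1000 bp on each side 8 lists passed, without trachea and with Dpp and chemoreceptors, and by gene span 9, with Dpp and chemoreceptors added.

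**Figure D2:**
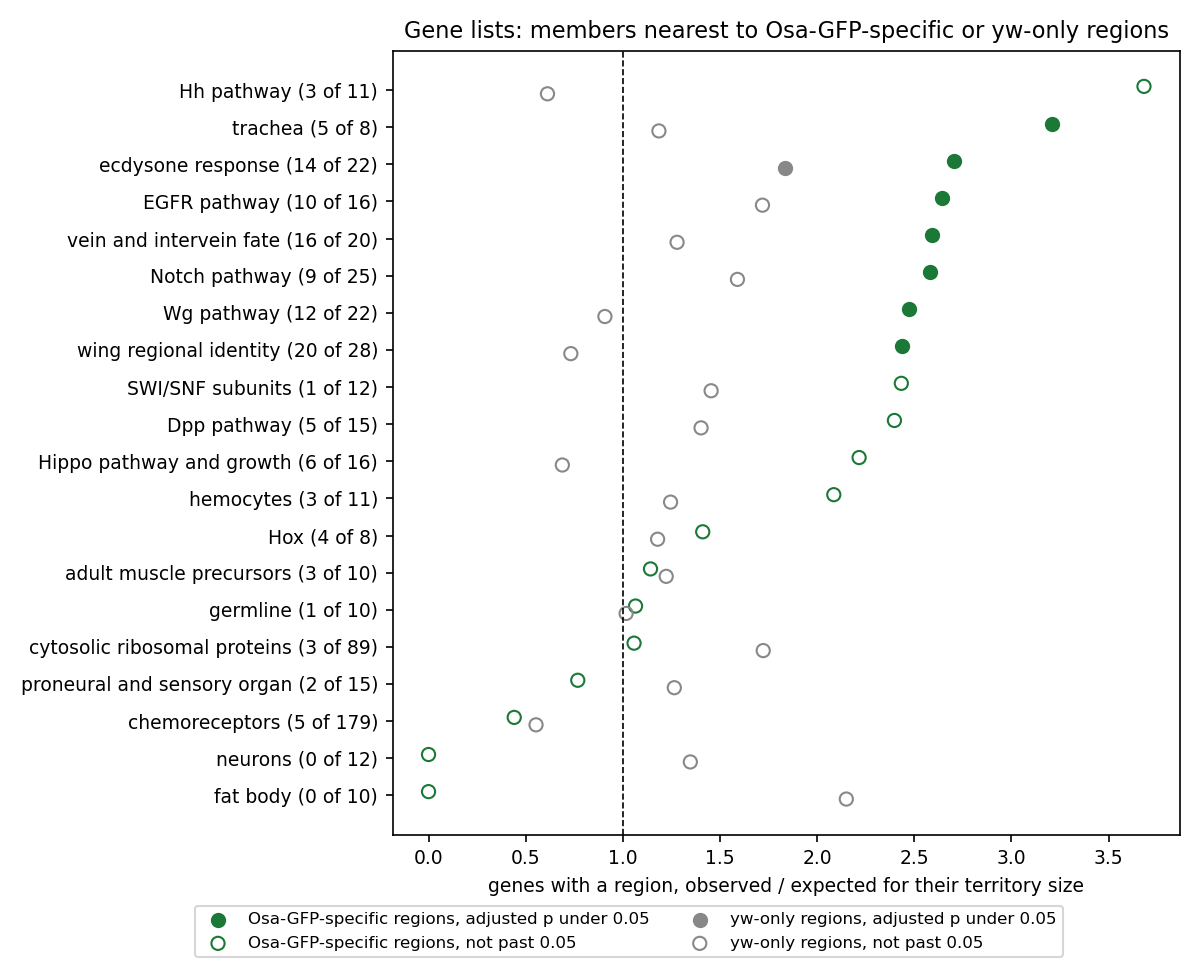
Ratio of observed to expected genes with a region (x axis) for each of the 20 gene lists (y axis, with the number of members that had an Osa-GFP-specific region). Shared regions, for which 10 lists passed, are not drawn. Green points are Osa-GFP-specific regions and grey points yw-only regions, filled where the adjusted p is under 0.05; wing regional identity lies at 2.44 for specific and 0.732 for yw-only regions, and ecdysone response at 2.70 and 1.83.

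For regions shared with the control 10 lists passed, 6 of which had passed for specific regions. They included wing identity with 15 of 28 genes (7.26 expected, 2.07 times, exact test, adjusted p = 0.0075) and veins with 15 of 20 (5.60 expected, 2.68 times). Notch passed with 14 of 25 (3.27 expected) and Dpp with 9 of 15 (1.91 expected). Wg, Hh, EGFR, Hippo and ecdysone response passed as well, and trachea did not (3 of 8, exact test, adjusted p = 0.388). Chemoreceptors passed with fewer genes than expected, 3 of 179 against 11.1. The difference between specific and shared regions was not tested by list. For all regions with a yw peak 5 lists passed: Notch, Dpp, EGFR and ecdysone response with more genes and chemoreceptors with fewer genes than expected. For yw-only regions 1 list passed, ecdysone response with 15 of 22 genes (8.18 expected, exact test, adjusted p = 0.0427). The named genes fell on both sides. Broad (br), an ecdysone-induced zinc finger gene, had 1 specific and 7 shared regions, and cut (ct), a homeobox gene of the wing margin, had no specific and 3 shared regions. nub had 4 specific and no yw region, Delta 5 specific and 3 shared, and N 4 specific and 8 shared. A shared region is one with a called yw peak, whatever its height. At the strongest shared region of hth, caller's folds were 34.0 and 27.4 in Osa-GFP replicates 1 and 2 and 8.10 in yw replicate 2. In the same order they were 42.8, 29.4 and 18.2 at Delta, 25.1, 19.2 and 39.2 at br, and 12.2, 6.16 and 18.9 at ct. Folds were not tested between lists.

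The difference between the sets was tested directly, after the list tests had been seen. Genes of wing regional identity took 3.57% of Osa-GFP-specific regions, 1.38% of all regions with a yw peak and 0.536% of yw-only regions. The permutation test gave an adjusted p of 0.0008 against the first and 0.0004 against the second, the latter from the smallest p the permutations can give. At −log10 q of 10 or more wing identity lost both of these calls. Against all regions with a yw peak no other list passed; the Wg list came next, with 1.87% and 0.809% of regions (permutation test, adjusted p = 0.0628). Against yw-only regions 7 lists passed, wing identity, veins, Notch, Wg, Hh, EGFR and Hippo, with adjusted p of up to 0.0480. The 2 sets of that last comparison were built unlike: specific regions needed peaks of 2 libraries, most yw-only regions held a peak of 1, and yw regions that met an Osa-GFP peak were left out of it. Against yw-only regions, veins and EGFR lost their calls at −log10 q of 10 or more and without yw replicate 2. Notch lost its call without Osa-GFP replicate 1, and veins and Hh lost theirs by gene body. The set of all regions with a yw peak was unlike in part as well, since 2611 of its 4698 regions were yw-only. Neither comparison can therefore tell a lack of yw peaks from peaks found again in a second library. Shared regions, which also needed peaks of both Osa-GFP libraries, had 44 of 1579 at wing identity and 37 at Notch. Specific regions had 63 of 1765 and 23.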

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

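The tests of list differences, the assignment by gene span, the use of the overlap settings on Osa-GFP replicate 1 with yw replicate 2 and the paired comparison were chosen after seeing the data; all other alternatives were fixed before the data were examined. The cause of changes was not tested. At −log10 q of 5 or more, 3270 peaks of Osa-GFP replicate 2, 208 of yw replicate 1 and 1737 of yw replicate 2 were left; at 10 or more, 2075 and 1619 Osa-GFP and 76 and 776 yw peaks. The 60.3% overlap of Osa-GFP replicate 1 with replicate 2 became 67.0% and 68.0% at these thresholds, 77.1% with the same number of peaks per list, 57.0% when overlaps had to cover 50% of the shorter peak and 54.4% for summits within 250 bp. Its 32.9% overlap with yw replicate 2 became 25.1%, 20.2%, 33.7%, 30.2% and 28.8% in the same order.

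The 1765 Osa-GFP-specific regions became 1001 at −log10 q of 10 or more, 463 with that threshold in the Osa-GFP lists alone, 347 with the same number of peaks per list and 3077 when only regions with peaks of both yw libraries were removed. Leaving out a library gave 1794 (without yw replicate 1) to 3863 (without Osa-GFP replicate 2), with 3055 without yw replicate 2 and 3154 without Osa-GFP replicate 1. The gene-end difference of -6.29 points became -1.20 points at −log10 q of 10 or more (Fisher's exact p = 0.53) and -2.13 points when both yw libraries had to hold a peak (exact p = 0.35). Leave-one-out values ran from -7.78 to -2.17 points, the last without yw replicate 2 (exact p = 0.28).

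The 7 lists past the threshold became 0 when only regions within 500 bp of a gene end were counted, where the Notch list had 0 genes, below its expectation, and the other 6 stayed above theirs. They became 14 with no correction for territory size (1 with fewer genes than expected) and 11 when both yw libraries had to hold a peak (2 with fewer). Leave-one-out counts ran from 7 to 11, the last without yw replicate 2 (2 with fewer). Vein, Wg, EGFR, Notch and ecdysone response kept their calls in 9 of the 10 alternatives, all but the count near gene ends. Wing identity lost its call in 2 alternatives and trachea in 6; Dpp and Hippo gained one in 7 each and Hh in 4. The 7 lists that differed from yw-only regions became 4 at −log10 q of 10 or more, without wing identity, veins and EGFR; the 1 list that differed from all regions with a yw peak became 2 by gene body and 2 by gene span, and 1 to 5 with a library left out, 5 without Osa-GFP replicate 2. At −log10 q of 10 or more it was the Wg list in place of wing identity. Of 682 counts of regions at named genes, 414 stayed within 1.5 times the reported count and 268 moved.

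The share of peaks near gene ends was a mean of 10.6 points higher in the yw lists (exact permutation p = 0.33). With the replicate number as replicate block it was 7.31 and 13.9 points higher (exact p = 0.5). These are the smallest p that 2 and 2 libraries and 2 pairs allow, and whether the numbers pair the samples is not known. Motifs under the summits and their 4 alternatives were not run. The few peaks of yw replicate 1 limit what it can remove as background, and 2 libraries per genotype allow no exact p below 0.33.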

Other observations

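In this part, the X share of strong peaks and the thinning at summit heights above the lowest were chosen only after the result was seen. Genes outside the lists also collected many Osa-GFP-specific regions. By the nearest gene end, CG43759 on X had 9, and CG14147, Tet, corto, a chromatin-associated protein gene, and Myo81F had 7 each; Myo81F also had 59 regions with a yw peak, against 3 at corto. By gene span, jing had 8, and brat, a translational repressor gene, and Svil had 7 each. These genes were picked after their values were seen. Of the Hox list, Antennapedia (Antp), which acts in the middle thoracic segment, had 16 by span where the nearest-end rule gave 5.

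Osa-GFP-specific regions lay next to each other. Of the 1765 regions, 65.4% had another within 10 kb. When each was replaced by a random position in the territory of a gene of the same size bin, the highest of 100 draws was 31.8%. The pattern was not special to regions without a yw peak: shared regions gave 59.6%, and specific regions thinned to the 1579 of that set gave 61.8%. yw-only regions thinned to the same number gave 26.7%. The draws do not model open chromatin, and no explanation was tested.

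Many regions of both Osa-GFP libraries also held a yw peak. Chance overlap of peaks placed anywhere on an arm is argued against: 47.2% held a yw peak, and shuffled yw peaks reached at most 4.28%. The shuffles do not model open chromatin, so they cannot decide on overlap of unrelated peaks within it. A background that follows the strength of the site stays open: 78.8% (75.5% to 81.7%) of the best 669 of 3344 regions by Osa-GFP rank held a yw peak and 30.0% (26.7% to 33.6%) of the worst 669. With yw summits required within 250 bp, which does not reward wide regions, these were 66.4% and 26.8%. The height of an Osa-GFP peak includes any signal that arises without GFP, so sites of high background can rank high without Osa. At the first region with peaks of all 4 libraries, caller's folds were 158 and 175 in Osa-GFP replicates 1 and 2. In yw replicates 1 and 2 they were 137 and 198. The trend with rank therefore cannot tell strong Osa sites from sites of high background. Whether the nuclease cuts Osa sites without GFP was not tested, and accessibility was not measured here.

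yw replicate 1 had 774 peaks and yw replicate 2 had 4535, at backgrounds of 0.120 and 0.481 fragments per position. Thinning the summit fragments of yw replicate 2 to the depth of yw replicate 1 left 1392 peaks at or above its lowest summit height, 1.80 times the number observed and outside the bound of 1.5 set beforehand for depth as the whole cause. At summit heights of 4 to 8 fragments or more the ratio was 1.38 to 1.53, close to that bound. The estimate uses only peaks that were called and no minimum length. Thinning can only lower the number, so the direction of the step from 4535 to 1392 carries no information. Depth as part of the cause was not decided and stays open. A different set of fragments is argued against for the strong peaks, of which 93.4% (71 of 76, 85.5% to 97.2%) overlapped yw replicate 2; of the weaker ones 44.0% did, and no biological explanation was tested, since both libraries are of 1 group.

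The X held 27.0% and 22.9% of the peaks of yw replicates 1 and 2 and 20.1% of those of each Osa-GFP library, against 17.5% of random positions. All discs were described as female. Peaks were also called on the Y, 13 and 16 in Osa-GFP replicates 1 and 2 and 4 and 25 in yw replicates 1 and 2. The origin of these Y peaks was not tested. More gene-end peaks in the yw lists are argued against, since away from gene ends the X share was 24.1% (22.6% to 25.6%) in yw replicate 2 and 20.1% (19.0% to 21.3%) in Osa-GFP replicate 1. Weak peaks near the threshold could not be excluded: at −log10 q of 10 or more the shares were 23.1% (20.2% to 26.2%) and 19.2% (17.6% to 21.0%), with intervals that meet. These shares lay no closer together than the 22.9% and 20.1% of all peaks of the same 2 libraries. With only 776 and 2075 peaks left, the intervals were wider. A difference between the strains on the X, which the genotypes could bring, was not tested.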
